A study of Homo sapiens with 12 samples.

How the data were processed

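The series holds 12 Affymetrix expression arrays of total RNA from 2 human acute myeloid leukaemia cell lines, U937 and MV4-11. Each line carried either an shRNA against the chromatin remodeler CHD4 or a scrambled shRNA, which gives 4 groups of 3 arrays. Per the labels' protocols, lentiviral vectors carrying green fluorescent protein delivered the hairpins, RNA was extracted with Trizol and biotinylated cRNA was hybridised. The sample labels spell the target CDH4 and the series description spells it CHD4. The groups are called CHD4 shRNA here because the CHD4 probe sets were lower in them, as reported first among the results. No probe set of CDH4 was named in the probe table, so that gene was not analysed here.

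The authors deposited 1 table of log2 values with 2 decimals, made with RMA per the submitters' processing notes. RMA corrects background, normalizes the arrays by quantiles and summarises the probes of each probe set. Its version, and whether all 12 arrays were processed together, are not given in the sources used here. The log2 scale was read from the values, which ran from 2.54 to 15.11, with array medians between 6.97 and 7.02. Quantile normalization fixes each array's distribution, so a change shared by most genes would not be seen. Background signal compresses the folds of dim genes, and no detection calls were used. The number of arrays limits the precision.

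The table held 22277 probe sets. Control probe sets, 62 in number, were left out. Of the others, 19070 had 1 gene symbol in the platform annotation, 1043 had several, and 2108 were not listed there and stayed unnamed. The Entrez identifiers of 19058 probe sets with 1 symbol were found in the RefSeq gene table. Probe sets with several symbols were not named. A gene was represented by its probe set with the highest mean over the 12 arrays, which gave 11963 genes, 4310 of them with more than 1 probe set. No filter on dim genes was applied.

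Comparisons used limma 3.58.1 in R 4.3.3. One linear model with the 4 groups was fitted to all 12 arrays (lmFit), followed by eBayes without trend, with 8 residual and 4.66 prior degrees of freedom. Contrasts were CHD4 shRNA minus scrambled in each line, the difference between these changes, and MV4-11 minus U937 scrambled controls. P-values were adjusted by Benjamini-Hochberg over the 11963 genes, and an adjusted p under 0.05 counted as past the threshold. Every adjusted p given for a gene comes from this limma fit. Exact permutation tests were two-sided, and with 3 arrays against 3 they cannot give a p below 0.1. Per the series description the triplicates were biological, and the p-values reflect the spread between these arrays.

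Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01. The 32 lists, with 956 members of which 813 were measured, were written from textbook knowledge and cover chromatin, DNA damage, cell cycle, metabolism, stress, inflammation, blood lineages, motility and other tissues. Adjustment was over the 32 lists. Each list was also tested with camera and an estimated correlation and with fry. Camera and fry with their adjusted p are the source of each p given for a list.

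Genes are named by a rule. In each line it takes the 6 largest rises and 6 largest falls past the threshold whose arrays did not overlap between groups. It adds the members with the lowest p from each list past camera, and from the NuRD, p53, double-strand break and motility lists whatever their result. For both lines it takes the 5 genes per direction with the largest smaller change, and for the scrambled controls the 6 largest differences per direction. Y-linked genes and XIST were not named, which leaves 4 genes in place of 6 on the side higher in MV4-11. The groups, tests, lists, naming rule and most alternatives were fixed before the data were examined. Exceptions are identified where they occur.

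Replicate numbers in the titles run from 1 to 3 in every group, so pairing was checked from each array's deviation from its group mean across genes. In MV4-11, scrambled and CHD4 shRNA arrays of the same number correlated at 0.46, 0.48 and 0.49, and the numbers were taken to pair these arrays. The pairing comes from the titles and this correlation, and the labels do not say what a number stands for. Blocked values are therefore given beside MV4-11 results where they change a call or move a count by over 1.5 times.

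Alternatives were leaving out the dimmest 25% of genes, quantile normalization or median centring of the deposited values, eBayes with trend and robust fitting, array weights, the mean of a gene's probe sets, all probe sets, only the groups compared, replicate blocks, other thresholds, other list tests, and leaving out each array in turn. A line score as a covariate and a replicate block within MV4-11 alone were added after seeing the data. The line score is the mean of 36 genes over 4-fold higher in MV4-11 than U937 scrambled arrays. The array weights did not converge and gave MV4-11 CHD4 shRNA replicate 1 a weight of 20.1, so fits with them lean on that array.

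The fit was tested on simulated data for the U937 comparison, drawn from the real means and spreads of the 11963 genes. Of the genes given a log2 change of 0.5, 28.4% were recovered, and of those given 1 or 2, 100% were. Among genes left unchanged, 6 passed the threshold. A list shifted by 0.5 was recovered and 0 of the other lists passed camera, but the simulated genes were independent of each other, which the real lists were not. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.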

Results

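Transcript levels were measured on 12 arrays from 2 leukaemia cell lines. U937 is a monocytic line, and MV4-11 is a myelomonocytic line that carries an MLL fusion and an activating FLT3 mutation. In each line, 3 arrays came from cells with an shRNA against CHD4 and 3 from cells with a scrambled shRNA. CHD4 is the ATPase of the nucleosome remodelling and deacetylase complex, NuRD. The series description asks how depletion of CHD4 affects the transcriptome of these cells. Values are log2 RMA values, means are over 3 arrays with their SD, and log2 changes are given with their standard error.

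CHD4 was lower with its shRNA in both lines. In U937 it went from 10.47 ± 0.21 to 8.27 ± 0.16 (SD, n = 3), which is 4.58-fold lower and leaves 21.8% of the control signal. In MV4-11 it went from 10.67 ± 0.02 to 8.68 ± 0.25 (SD, n = 3), which is 3.99-fold lower and leaves 25.1%. The limma adjusted p was 8.78e-06 in U937 and 1.35e-05 in MV4-11, and all 3 CHD4 probe sets were past the threshold in both lines, between 3.36-fold and 4.58-fold lower. The arrays of the groups did not overlap in either line (exact permutation p = 0.1, the smallest that 3 against 3 can give). The log2 change differed between the lines by 0.20 (SE 0.20, adjusted p = 0.94).

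**Figure D1:**
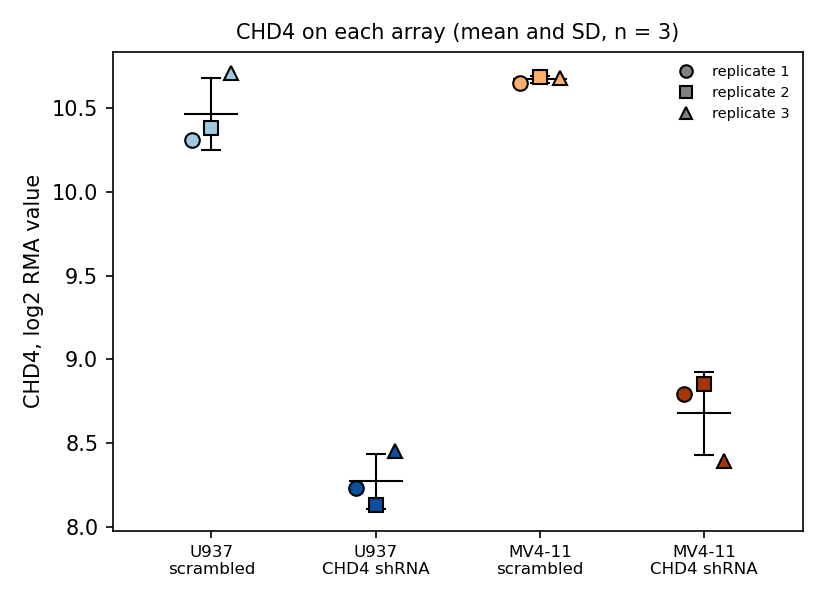
Log2 RMA value of CHD4 on each of the 12 arrays, by group; symbols mark the replicate number, and bars give the mean and SD of 3 arrays. The CHD4 shRNA arrays lie between 8.13 and 8.85, below the scrambled arrays, which lie between 10.31 and 10.71.

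In U937, CD52, a surface glycoprotein of lymphocytes and monocytes, had the largest rise with CHD4 shRNA, by a log2 of 4.38 (SE 0.32), from 5.60 ± 0.43 to 9.98 ± 0.72 (SD, n = 3). S100A7, a calcium-binding antimicrobial protein, rose by 3.24 (SE 0.22), and the testis gene TSKS and the muscle gene CSRP3 each by 2.89. The scavenger receptor CD36 rose by 2.48 (SE 0.52) and the interleukin-1 decoy receptor IL1R2 by 2.47 (SE 0.24). Besides CHD4, the largest falls were CAB39L at -2.02 (SE 0.42), the RNA polymerase III subunit POLR3G at -1.92 (SE 0.23), GNPDA1 at -1.86, MNS1 at -1.79 and the B-cell adaptor BLNK at -1.78. Other probe sets of TSKS, POLR3G and CD36 showed changes of 0.46, -0.29 and 0.35, not past the threshold.

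Of the 11963 genes, 761 changed in U937, 320 higher and 441 lower, and 55 of the rises and 51 of the falls were at least 2-fold. Leaving out 1 array lowered the count to 328 (scrambled replicate 1), 416 (scrambled replicate 2), 393 (scrambled replicate 3), 306 (CHD4 shRNA replicate 2) or 363 (CHD4 shRNA replicate 3).

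List results below rest on camera with the preset correlation, since 0 lists passed with an estimated correlation or with fry in either line. In each line 7 of 10 splits of the arrays gave at least as many lists past camera as the real grouping. Chance is therefore not excluded for the number of lists. The cholesterol and fatty acid synthesis list fell in U937 (camera adjusted p = 0.00012; adjusted p = 0.87 with an estimated correlation). Of its 20 measured members 4 fell and 0 rose, or 5 and 0 adjusted over the list alone. IDI1, which isomerises isopentenyl diphosphate, had a log2 change of -0.83 (SE 0.19), the sterol desaturase SC5D of -0.81 (SE 0.19) and the mevalonate pathway kinase PMVK of -0.64 (SE 0.11). Another probe set of SC5D, at -0.01, was not past the threshold. The list of MYC and ribosome biogenesis genes fell as well (adjusted p = 0.00012; adjusted p = 0.87 with an estimated correlation), with 3 of 21 members lower, 5 adjusted over the list alone. They were MYC at -0.83 (SE 0.20), the acetyltransferase NAT10 at -0.51 and CAD, which starts pyrimidine synthesis, at -0.48. In the unfolded protein response and amino acid stress list 6 of 26 members fell and 1 rose, or 10 and 2 adjusted over the list alone (adjusted p = 0.00017; adjusted p = 0.87 with an estimated correlation). The cystine transporter SLC7A11 changed by -1.12 (SE 0.23), with another probe set at -0.32 and not past the threshold, the serine synthesis enzyme PSAT1 by -0.65 (SE 0.14) and the stress transcription factor ATF4 by -0.41 (SE 0.09). SLC7A11 stood at -1.58, PSAT1 at -0.88 and ATF4 at -0.52 from the scrambled mean in CHD4 shRNA replicate 3, the lowest of the 3 arrays for each. That array also lay farthest from the others of its group on the second principal component, at -27.66.

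Higher groups in U937 included monocyte and motility genes. In the monocyte and macrophage list 4 of 32 members rose and 1 fell, or 5 and 1 adjusted over the list alone (camera adjusted p = 0.032; adjusted p = 0.87 with an estimated correlation). The Fc receptor chain FCER1G rose by 1.25 (SE 0.20) and AIF1 by 0.46 (SE 0.09), with another AIF1 probe set at 0.05 and not past the threshold, whereas the lysosomal protease CTSD fell by 0.62 on the log2 scale (SE 0.11). This call was lost without scrambled replicate 3 (adjusted p = 0.39) and without CHD4 shRNA replicate 3 (adjusted p = 0.059), without the dimmest 25% of genes (0.117) and with array weights (0.206). In the motility, adhesion and matrix list 6 of 48 members rose and 3 fell, or 9 and 4 adjusted over the list alone (adjusted p = 0.044; adjusted p = 0.87 with an estimated correlation). The gelatinase MMP9 rose by 1.69 (SE 0.21) and the galectin LGALS1 by 0.87 (SE 0.13), and the chemokine receptor CXCR4 fell by 0.94 on the log2 scale (SE 0.11). This second call was lost in 7 of 12 fits without 1 array. The adjusted p was 0.051 without U937 scrambled replicate 1, 0.28 without U937 scrambled replicate 3, and 0.051 and 0.059 without U937 CHD4 shRNA replicates 2 and 3. It was 0.053 and 0.054 without MV4-11 scrambled replicates 1 and 3, and 0.054 without MV4-11 CHD4 shRNA replicate 1. The call was also lost without the dimmest 25% of genes (0.089), with array weights (0.125), with the mean of a gene's probe sets (0.219) and with only the U937 arrays (0.072).

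The G2/M and mitosis list also ranked higher in U937 (camera adjusted p = 0.00012; adjusted p = 0.87 with an estimated correlation), with a median log2 change of 0.23. None of its 30 members passed the limma threshold, over all genes or adjusted over the list alone; UBE2C had a change of 0.69 (adjusted p = 0.061). The NuRD list did not pass (adjusted p = 0.74), and its median of 0.06 and mean of -0.07 differ in sign; of its 13 members CHD4 alone was past the threshold, while CDK2AP1 had a change of 0.67 (adjusted p = 0.065). The double-strand break repair list did not pass (adjusted p = 0.21), although 4 of its 34 members fell and 0 rose, counts that are the same adjusted over the list alone. Among them were the checkpoint kinase CHEK2 at -0.78 (SE 0.17) and the damage mediator MDC1 at -0.72 (SE 0.12), whose second probe set, at -0.51, was not past the threshold. In the p53 target list (adjusted p = 0.52) RPS27L rose by 0.57 and GADD45A fell by 0.70 on the log2 scale, which is 1 up and 1 down of 23, or 1 and 2 adjusted over the list alone. In all, 26 of the 32 lists did not pass, 4 of which passed in a fit without 1 array, and the lowest adjusted p among lymphoid, erythroid, mast cell, muscle, neuronal, fibroblast and epithelial lists was 0.15.

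In MV4-11, CD52 again had the largest rise, by a log2 of 4.68 (SE 0.32), from 6.68 ± 0.37 to 11.36 ± 0.34 (SD, n = 3). It was followed by the G protein-coupled receptor GPR18 at 3.77 (SE 0.70), the interferon-induced gene IFI27 at 3.21 (SE 0.66), the adhesion molecule CEACAM6 at 3.16 (SE 0.27), the secretory granule protein CHGB at 2.60 (SE 0.28) and the interferon-induced IFI44 at 2.60 (SE 0.35). The largest fall was CAB39L, with a log2 change of -3.06 (SE 0.42), then BLNK at -2.20 (SE 0.43), TESMIN at -2.03 (SE 0.54), CHD4, the calcium-binding protein SRI at -1.64 (SE 0.15) and the glycosyltransferase GALNT3 at -1.62 (SE 0.30). A second probe set of GALNT3 had a change of -0.07 and a second one of IFI44 a change of 0.25, neither past the threshold. TESMIN was not past the threshold with a replicate block shared by both lines (adjusted p = 0.060).

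In this line 1127 genes changed, 566 higher and 561 lower, with 135 rises and 56 falls of at least 2-fold. With a replicate block within each line the count was 2351, and 1903 with the block in MV4-11 alone. With only the MV4-11 arrays in the fit it was 513. It was 422 without CHD4 shRNA replicate 1, 637 without CHD4 shRNA replicate 2, 1964 without CHD4 shRNA replicate 3, 647 without scrambled replicate 2 and 599 without scrambled replicate 3.

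Of 30 measured members of the interferon list, 10 rose and 1 fell in MV4-11, or 16 and 3 adjusted over the list alone (camera adjusted p = 8.88e-06; adjusted p = 0.93 with an estimated correlation), and the median log2 change was 0.45, or 0.24 without CHD4 shRNA replicate 2. IFI6 rose by 1.84 (SE 0.25), beside IFI27 and IFI44. Camera also passed the list in 8 of the other splits of the MV4-11 arrays, so its p carries little weight here. In U937 the list did not pass (adjusted p = 0.52), with 2 members higher and 2 lower, or 4 and 3 adjusted over the list alone. The list's median stood above the scrambled mean by 0.34, 0.97 and 0.24 in CHD4 shRNA replicates 1, 2 and 3, so replicate 2 had the highest interferon signal. That array also lay farthest along the first principal component, which held 39.5% of the variance.

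The amino acid stress list fell in MV4-11 too, with 8 of 26 members lower and 1 higher, or 13 and 1 adjusted over the list alone (camera adjusted p = 0.00061; adjusted p = 0.93 with an estimated correlation). Asparagine synthetase, ASNS, changed by -1.48 (SE 0.23), PSAT1 by -0.87 (SE 0.14) and the ATF4 target TRIB3 by -0.77 (SE 0.13). Of 24 replication-dependent histone genes 6 rose and 0 fell, or 8 and 0 adjusted over the list alone (adjusted p = 0.00061; adjusted p = 0.93 with an estimated correlation). H2BC12 rose by 2.01 (SE 0.44), H2BC5 by 1.58 (SE 0.36) and H2BC9 by 1.35 (SE 0.32). The histone list's median stood at 0.21, 0.60 and 0.05 from the scrambled mean in CHD4 shRNA replicates 1, 2 and 3, and at 0.18 in scrambled replicate 2. H2BC12 ran from 10.50 to 13.01 over the 3 CHD4 shRNA arrays, and the list still passed without CHD4 shRNA replicate 2 (adjusted p = 0.0048).

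In the monocyte and macrophage list 6 of 32 members rose and 2 fell, or 8 and 3 adjusted over the list alone (camera adjusted p = 0.0071; adjusted p = 0.93 with an estimated correlation). FCER1G rose by 1.41 (SE 0.20) and the integrin ITGAM by 1.41 (SE 0.21), with a second ITGAM probe set at -0.11, and CTSD fell by 0.71 on the log2 scale (SE 0.11). The immediate early and AP-1 list passed upward (adjusted p = 0.0071; adjusted p = 0.93 with an estimated correlation), but over all genes 1 member rose and 1 fell, or 3 and 1 adjusted over the list alone. These were the MAP kinase phosphatase DUSP6 at 1.73 (SE 0.41) and MYC at -0.89 (SE 0.20); IER3, at 1.40, had an adjusted p of 0.056, and of 0.044 and 0.027 with the replicate block within each line and in MV4-11 alone. Without CHD4 shRNA replicate 2 both calls were lost (adjusted p = 0.13 and 0.73), and the monocyte call was lost with array weights (0.098).

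Cell cycle lists passed upward in MV4-11 with few members past the threshold. For DNA replication and G1/S (camera adjusted p = 0.0071; adjusted p = 0.93 with an estimated correlation) the cyclin CCNE2 rose by 1.31 (SE 0.33), 1 of 35 members over all genes and 0 adjusted over the list alone. LIG1, at -0.34, and RFC4, at -0.38, had an adjusted p of 0.070 and 0.072, and with the replicate block within each line 0.047 and 0.021. With the block in MV4-11 alone LIG1 passed (0.047), and with a block shared by both lines RFC4 passed (0.039). The DNA replication and G1/S call was lost without CHD4 shRNA replicate 2 (adjusted p = 0.14) and without scrambled replicate 3 (adjusted p = 0.26). For G2/M and mitosis (adjusted p = 0.038; adjusted p = 0.93 with an estimated correlation) 0 of 30 members passed limma on either count, and KIF11 had a change of 0.42 (adjusted p = 0.062) and ESPL1 one of 0.54 (0.073), while another ESPL1 probe set, at 0.52, was past the threshold (0.038). With the replicate block within each line KIF11 (0.0076), PLK1 (0.027) and ESPL1 (0.016) passed, and with the block in MV4-11 alone ESPL1 (0.029). The G2/M call was lost without scrambled replicate 1 (adjusted p = 0.19), scrambled replicate 2 (adjusted p = 0.069) or CHD4 shRNA replicate 3 (adjusted p = 0.62), and with the replicate block in MV4-11 alone (adjusted p = 0.064). It was lost as well without the dimmest 25% of genes (0.083), with quantile normalization of the deposited values (0.052) and with array weights (0.064).

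The remaining 25 lists did not pass in MV4-11, although 7 of them passed under at least 1 alternative. With camera on ranks the NuRD list passed upward (adjusted p = 0.045), and cholesterol synthesis (0.037) and cytosolic ribosomal proteins (0.027) passed downward. Each of these 3 had an adjusted p = 0.93 with an estimated correlation. All 26 ribosomal members had a change below 0, with a median of -0.06 and 0 past the threshold. In the p53 target list (adjusted p = 0.059) 3 of 23 members rose and 0 fell on both counts, the one over all genes and the one adjusted over the list alone, among them TP53I3 by 0.98 (SE 0.28) and RPS27L by 0.53 (SE 0.09). With the replicate block in MV4-11 alone this list passed (adjusted p = 0.049), as did the heat shock list (0.059 without and 0.049 with the block). Without the block both had an adjusted p = 0.93 with an estimated correlation, and 0.41 and 0.23 with fry. In the double-strand break list (adjusted p = 0.91) 1 of 34 members rose and 3 fell, or 3 and 3 adjusted over the list alone, with MDC1 at -0.90 (SE 0.12) and CHEK2 at -0.89 (SE 0.17); its median was above 0, its mean was -0.05 and its test pointed down. In the NuRD list (adjusted p = 0.11) CDK2AP1 rose by 1.12 (SE 0.20), and 2 of 13 members rose and 1 fell, or 3 and 1 adjusted over the list alone. The motility list did not pass (adjusted p = 0.059), with 7 of 48 higher and 4 lower, or 10 and 4 adjusted over the list alone; CXCR4 changed by -1.02 (SE 0.11) and the integrin ITGA6 by -0.91 (SE 0.13). Among the lymphoid, erythroid, mast cell, muscle, neuronal, fibroblast and epithelial lists the lowest adjusted p was 0.555.

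The same genes tended to change in both lines. CD52, S100A7, CD36, IL1R2 and the aldo-keto reductase AKR1C3 were the strongest shared rises, although another CD36 probe set, at 0.16 in MV4-11, was not past the threshold; AKR1C3 rose by 2.19 in U937 and 2.17 in MV4-11 (SE 0.43 in each). CHD4, CAB39L, BLNK, MNS1 and the amidating enzyme PAM were the strongest shared falls; PAM changed by -1.34 in U937 and -1.36 in MV4-11 (SE 0.12 in each). Of the genes past the threshold, 204 rose in both lines, where 15 would be shared by independent lists (one-sided Fisher exact test over genes, p = 2.07e-200), and 273 fell in both, against 20.7 (p = 3.91e-273). That makes 477 genes, and 0 changed in opposite directions. The calls of both lines use 1 spread per gene pooled over the 4 groups. A gene with a small spread therefore tends to pass in both, which the expected counts and the Fisher test do not allow for. Across all 11963 genes the log2 changes of the lines correlated at Pearson r = 0.71 and Spearman rho = 0.57; genes are not independent replicates, and each line had its own controls. The sign was shared by 98.4% of the genes that changed in U937 and by 97.8% of those that changed in MV4-11. Scrambled arrays of the 2 lines correlated at a mean r of 0.987, and the identity of the MV4-11 cultures stays open. The sharing may therefore not be that of 2 unrelated lines, and effects of the hairpin other than CHD4 loss were not tested.

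The count of 477 became 961 with a replicate block within each line, 754 with the block in MV4-11 alone, and 310 with each line fitted alone. Leaving out 1 array gave 238, 289 and 271 (U937 scrambled replicates 1, 2 and 3), 235 and 266 (U937 CHD4 shRNA replicates 2 and 3), 316 (MV4-11 scrambled replicate 2) or 237 (MV4-11 CHD4 shRNA replicate 1).

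**Figure D2:**
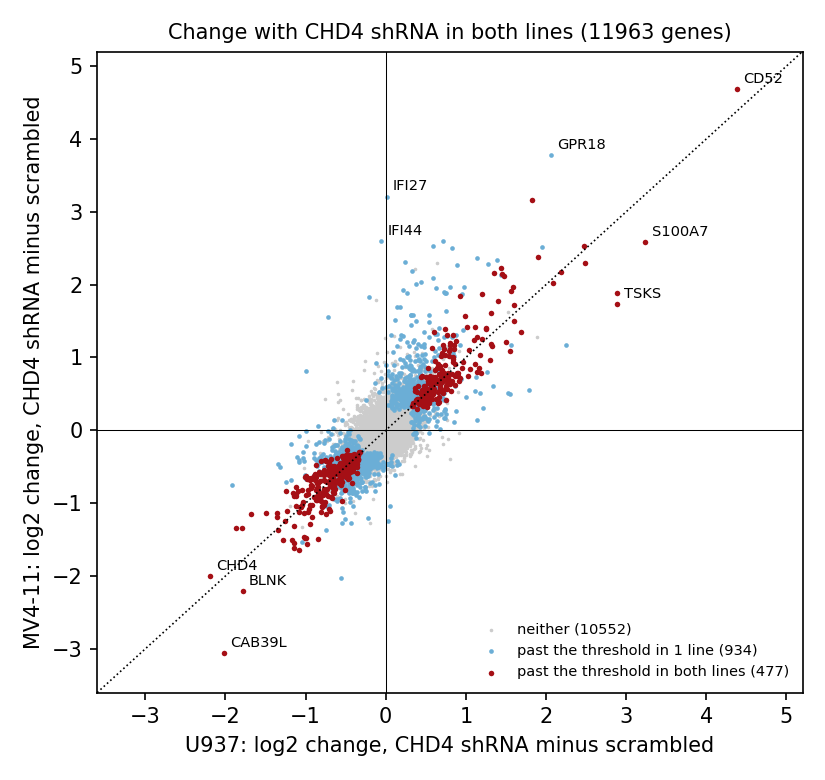
Log2 change with CHD4 shRNA in U937 (horizontal axis) and MV4-11 (vertical axis) for 11963 genes; each point is a gene, and the dotted line marks equal change. The 477 genes past the threshold in both lines (dark red) lie in the quadrants of shared direction, 934 genes passed in 1 line (blue), and IFI27 and IFI44 lie near 0 in U937.

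Whether the response differed between the lines was tested with the interaction contrast. The widest gaps among the interferon genes were IFI27, with changes of 0.01 in U937 and 3.21 in MV4-11, and IFI44, with -0.05 and 2.60. Their differences of 3.20 (SE 0.93, adjusted p = 0.94) and 2.65 (SE 0.50, adjusted p = 0.54) did not pass. By limma 0 of the 11963 genes passed, with 546 at an unadjusted p under 0.05. With array weights, which did not converge and lean on MV4-11 CHD4 shRNA replicate 1, 119 passed. Without MV4-11 CHD4 shRNA replicate 2, 4 genes passed, all higher in MV4-11: IFI44 (difference 2.04, adjusted p = 2.79e-05), IFI27 (2.04, adjusted p = 9.27e-05), MX1 (1.11, adjusted p = 0.0047) and TM6SF1 (1.43, adjusted p = 0.027). Without MV4-11 CHD4 shRNA replicate 3, CHGB passed (2.28, adjusted p = 0.016). MX1 and TM6SF1 are named because of these counts, after their values were seen.

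On the same contrast, tested with camera, 73 of 100 drawn splits of the arrays gave 6 or more lists, so chance is not excluded for their number. In the real grouping 6 lists had a more positive change in MV4-11. They were the interferon list (median difference 0.45, adjusted p = 1.22e-07), DNA replication and G1/S (0.29, adjusted p = 2.24e-06), heat shock proteins (0.27, adjusted p = 0.0020), histones (0.32, adjusted p = 0.0048), MYC and ribosome biogenesis (0.19, adjusted p = 0.016) and oxidative phosphorylation (0.09, adjusted p = 0.036). Each of the 6 had an adjusted p = 0.86 with an estimated correlation, and none of their members passed over all genes; adjusted over the list alone, 1 interferon gene passed and 0 in the other 5. The oxidative phosphorylation call was lost with the replicate block within each line (adjusted p = 0.051). Under that block NuRD (adjusted p = 0.027) and cholesterol synthesis (adjusted p = 0.036) passed upward, and G2/M (adjusted p = 0.036) passed downward. With the block in MV4-11 alone, oxidative phosphorylation was lost (adjusted p = 0.059), and cholesterol synthesis (0.027) and immediate early genes (0.047) passed upward. With camera on ranks these 2 lists passed as well (0.034 and 0.036). Without a block, NuRD, cholesterol synthesis, G2/M and immediate early genes each had an adjusted p = 0.86 with an estimated correlation and 0.83 with fry, and 0 of their members passed over all genes. The histone call was lost without MV4-11 scrambled replicate 1 (adjusted p = 0.105) and without MV4-11 CHD4 shRNA replicate 2 (0.058). The MYC and ribosome biogenesis call was lost without U937 scrambled replicate 3 (0.233), U937 CHD4 shRNA replicate 2 (0.085), MV4-11 scrambled replicate 3 (0.231), or MV4-11 CHD4 shRNA replicate 1 (0.053) or 2 (0.545). The oxidative phosphorylation call was lost without U937 scrambled replicate 3 (0.134), U937 CHD4 shRNA replicate 2 (0.085) or 3 (0.062), MV4-11 scrambled replicate 1 (0.074) or 3 (0.156), or MV4-11 CHD4 shRNA replicate 3 (0.168). It was also lost without the dimmest 25% of genes (0.073), with quantile normalization of the deposited values (0.10), with array weights (0.227) and with the mean of a gene's probe sets (0.067).

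**Figure D3:**
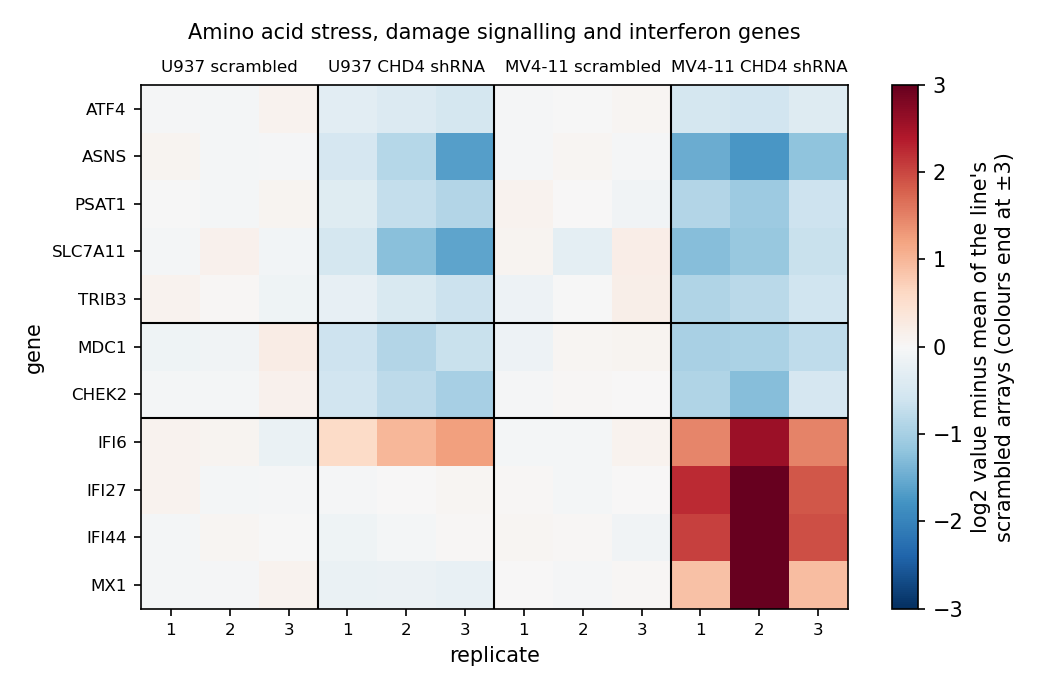
Log2 value of each array minus the mean of its line's 3 scrambled arrays, for 11 genes (rows) on 12 arrays (columns, replicate numbers within groups); colours end at 3 on either side. ATF4, ASNS, PSAT1, SLC7A11, TRIB3, MDC1 and CHEK2 are below 0 on all 6 CHD4 shRNA arrays, IFI6 is above 0 on all 6, and IFI27, IFI44 and MX1 are at 0.88 or more on the CHD4 shRNA arrays of MV4-11, highest in replicate 2.

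Between the scrambled controls, MV4-11 had far more of the nucleosome-binding protein HMGN3, 9.17 ± 0.60 against 3.92 ± 0.44 in U937 (SD, n = 3), a log2 difference of 5.26 (SE 0.29). SDCBP was higher by 4.71 (SE 0.46), the neuronal navigator NAV3 by 4.18 (SE 0.43) and the myeloid transcription factor CEBPD by 3.85 (SE 0.40). U937 had more HDGFL3, with a difference of -3.53 (SE 0.20), the defensin DEFB1 at -3.47 (SE 0.21), the heparan sulfate enzyme HS3ST2 at -3.12 (SE 0.28), LAMP5 at -3.07 (SE 0.32), DLK1 at -2.80 (SE 0.32) and the myeloid lectin CLEC5A at -2.56 (SE 0.38). The other probe sets of NAV3 and CEBPD, between -0.16 and 0.49, and 1 of HDGFL3, at -0.40, were not past the threshold.

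In all 655 genes differed, 355 higher and 300 lower in MV4-11, with 105 and 54 of these at least 2-fold. The lines were otherwise alike: 93.3% of genes lay within 0.5 log2 units, and scrambled arrays of different lines correlated at a mean r of 0.987 across genes, against 0.996 within U937 and 0.994 within MV4-11. Scrambled and CHD4 shRNA arrays correlated at a mean r of 0.990 within U937 and 0.986 within MV4-11. The controls of the 2 lines were thus about as close as the hairpin groups within a line. The lines are identified by their labels. Leaving out U937 scrambled replicate 1 or 2 gave 317 or 325 genes, and leaving out MV4-11 scrambled replicate 2 or 3 gave 339 or 340.

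The genes marking MV4-11 varied together between its arrays. The mean of the 36 genes over 4-fold higher in MV4-11 was 7.04, 8.37 and 7.84 in scrambled replicates 1, 2 and 3, and 7.62, 8.52 and 7.49 in the CHD4 shRNA replicates. Its group means were 7.75 ± 0.67 and 7.88 ± 0.56 (SD, n = 3, exact permutation p = 0.9, where the smallest possible is 0.1). These genes were chosen on the scrambled arrays, which favours that group. The 48 such genes chosen on the CHD4 shRNA arrays had means of 6.56, 7.65 and 7.15 in scrambled replicates 1, 2 and 3. In the CHD4 shRNA replicates, which that choice favours, they had 7.51, 8.73 and 7.31, higher for each replicate number. An equal marker level in the 2 groups is therefore not shown. In U937 the means of the 36 genes were 4.84 in scrambled and 5.04 in CHD4 shRNA arrays, and the 3 CHD4 shRNA arrays lay above the 3 scrambled arrays (exact permutation p = 0.1). Choosing genes that were low in the U937 scrambled arrays favours that order. The 48 genes, whose choice favours the reverse, had 4.94, 4.91 and 4.78 in U937 scrambled replicates 1, 2 and 3. In the U937 CHD4 shRNA replicates they had 4.97, 5.01 and 5.09.

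**Figure D4:**
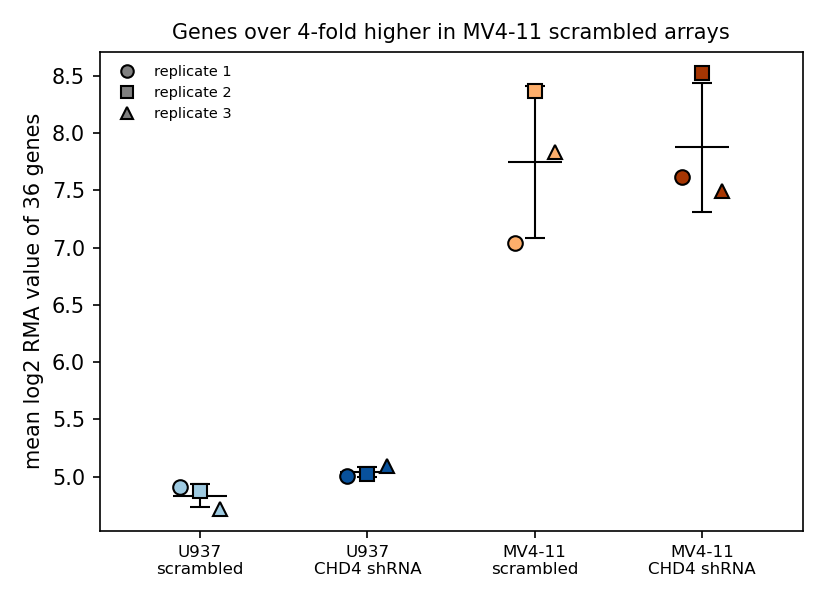
Mean log2 RMA value of the 36 genes over 4-fold higher in MV4-11 than U937 scrambled arrays, on each array; symbols mark the replicate number, and bars give the mean and SD of 3 arrays. The MV4-11 arrays spread from 7.04 to 8.52 and all lie above the U937 arrays.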

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

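The tests of chance over other splits of the arrays were chosen before the data were examined, but apart from that of the interferon list they were written out after the counts had been seen, and the other tests on the interferon genes were chosen only after the result was seen.

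The change with CHD4 shRNA differed between the lines for 6 gene lists by camera on the interaction contrast, all more positive in MV4-11. With an estimated correlation each had an adjusted p = 0.86, and fry passed 0 of the lists (lowest adjusted p = 0.83). By camera the adjusted p was 1.22e-07 for interferon response, 2.24e-06 for DNA replication and G1/S, 0.0020 for heat shock proteins, 0.0048 for replication-dependent histones, 0.016 for MYC and ribosome biogenesis and 0.036 for oxidative phosphorylation. Of 100 drawn splits of the arrays within both lines, 73 gave 6 or more lists, with 15 as the highest of the other splits, so chance is not excluded for the number of lists. In U937, 7 of 10 splits gave as many as the real 6 lists (highest other 13), and in MV4-11, 7 of 10 gave as many as the real 7 (highest other 13); 10 splits are too few for a share under 0.05.

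Of 30 interferon genes 10 rose and 1 fell in MV4-11, with a median change of 0.45 for the list, and in 1 of the 10 splits of the MV4-11 arrays, the real one, the median was as large, and the highest of the others was 0.44; 10 splits are too few for a share under 0.05. Camera itself passed the list in 8 of the other 9 splits, so its p carries little weight for these co-varying genes. CHD4 shRNA replicate 2 alone as the cause is argued against, because 6 members were still called as rises without it, although the list's median was then 0.24. Whether an unequal share of cells with the MV4-11 marker genes was the cause is not decided. Over all 30 members, 23 were higher in CHD4 shRNA replicates 1 and 3 than in scrambled replicates 2 and 3. The median difference was 0.29, with quartiles of 0.03 and 0.81. Scrambled replicates 2 and 3 had the higher marker levels only by the genes chosen on the scrambled arrays. By the genes chosen on the CHD4 shRNA arrays, scrambled replicates 2 and 3 had means of 7.65 and 7.15. CHD4 shRNA replicates 1 and 3 had 7.51 and 7.31 by that choice. An unequal share therefore stays open. A response to CHD4 loss or another effect of this hairpin could each underlie the interferon rises and stay open too, since neither was tested. The scrambled controls also carried a lentiviral hairpin vector.

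Among the 2108 probe sets without a gene in the probe table, which the comparisons by gene do not use, 53 passed the limma threshold in U937 and 79 in MV4-11. Of the 62 control probe sets, 0 passed in either line.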

How the results depend on the processing

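The replicate block in MV4-11 alone and the line score as a covariate were chosen after seeing the data. Of the 90 results for named genes, 1901 of 2063 alternatives kept the direction and side of the threshold, 115 lost the call, 47 gained one and 0 turned direction. CHD4 stayed past the threshold in every alternative run, between -2.29 and -2.08 in U937 and between -2.08 and -1.85 in MV4-11 when 1 array was left out.

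Gene counts in U937, MV4-11, between scrambled controls and in both lines were 1397, 4366, 1492 and 1042 with array weights, which also gave 119 genes for the interaction; the weights did not converge, and MV4-11 CHD4 shRNA replicate 1 took a weight of 20.1. With a replicate block within each line they were 1474, 2351, 1617 and 961. U937 arrays of the same number correlated at 0.0023, 0.35 and 0.34, which does not pair them, and the block ended the U937 monocyte (adjusted p = 0.053) and motility (0.073) list calls and brought UBE2C, CDK2AP1, KIF20A and NUSAP1 past the threshold there; replicates 2 and 3 correlated best with their own number and replicate 1 did not. The block in MV4-11 alone gave 1903 there and 754 in both lines. In U937 a block shared by both lines ended the calls of MYC (adjusted p = 0.051) and NAT10 (0.068). It brought KIF20A (0.040) and NUSAP1 (0.025) past the threshold there. At an adjusted p under 0.01 the counts were 250, 376, 267 and 139, and with a change of at least 1.5-fold 407, 600, 387 and 246, fewer by construction. With only the groups compared they were 846, 513, 826 and 310, and all probe sets gave 988 between scrambled controls. Leaving out 1 array gave 306 to 947 genes in U937, 422 to 1964 in MV4-11, 0 to 4 for the interaction, 317 to 844 between scrambled controls and 235 to 568 in both lines. With an estimated correlation 0 lists passed in U937, 0 in MV4-11 and 0 for the interaction (1, 1 and 0 at an unadjusted p under 0.05), and with fry 0, 0 and 0 (5, 4 and 0 unadjusted), against 8, 14 and 10 unadjusted with camera. Of the lists that did not pass, 4 of 26 in U937, 7 of 25 in MV4-11 and 10 of 26 for the interaction passed under some alternative, 4, 1 and 5 of them only when 1 array was left out. With the line score as a covariate 1180 genes passed in MV4-11. Except where stated, the cause of these shifts was not tested. Signal over background limits the folds of dim genes.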

Other observations

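The tests of chance were planned, but apart from that of the interferon list they were written out after the counts had been seen; among the others, only the test of whether dim genes can fall further was written before its result was seen. The genes in the first paragraphs were chosen after their values were seen.

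Of 12 measured genes of antigen presentation by HLA class II, 10 had a change below 0 in U937 and 6 had one above 0 in MV4-11, most of them small, and 0 passed limma in opposite directions. HLA-DRA changed by -0.99 in U937 (limma adjusted p = 0.039) and by 0.82 in MV4-11 (adjusted p = 0.065), and HLA-DPA1 by -0.72 (adjusted p = 0.20) and 1.55 (adjusted p = 0.0076). HLA-DRB1 fell in U937, at -0.99 (adjusted p = 0.0016), and HLA-DMA at -1.18 (adjusted p = 0.032), while HLA-DPB1 rose in MV4-11, at 0.42 (adjusted p = 0.038). No difference between the lines passed over all genes. The differences between the lines, 1.81 for HLA-DRA and 2.27 for HLA-DPA1, had an adjusted p of 0.56 and 0.54.

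The glycolysis and hypoxia list did not pass camera (adjusted p = 0.18 in U937 and 0.97 in MV4-11). Of its 28 measured members 5 fell and 0 rose in U937, or 5 and 0 adjusted over the list alone, and 5 fell and 1 rose in MV4-11, or 7 and 1 adjusted over the list alone; the 5 were shared, and ENO2 rose, by 0.57. The hexokinase HK2 changed by -0.77 in U937 and -0.68 in MV4-11, the kinase PDK1 by -0.86 and -0.73, the growth factor VEGFA by -0.57 and -0.71, the isomerase GPI by -0.39 and -0.37, and DDIT4 by -0.85 and -0.95. The list of granulocytic precursor and granule genes did not pass either (adjusted p = 0.65 in U937 and 0.11 in MV4-11). Of its 24 members 2 rose and 2 fell in U937, or 2 and 3 adjusted over the list alone, and 3 rose and 3 fell in MV4-11, or 6 and 3 adjusted over the list alone. The defensin DEFA4 rose by 1.20 in U937 and 1.26 in MV4-11, MMP9 by 1.69 and 1.35, and RNASE2 by 0.72 in MV4-11. Elastase, ELANE, changed by -0.82 and -0.69, CEACAM8 by -0.46 in U937, and CTSG and CD24 by -0.74 and -0.77 in MV4-11.

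The gene counts were set against other splits of the arrays. In U937, 1 of 10 splits, the real one, gave as many as 761 genes, with 0 as the highest of the others, and between the scrambled controls 1 of 10 gave as many as 655, with 0 as the highest other. In MV4-11, 1 of 10 splits gave as many as 1127, with 2 as the highest other; of the 4 splits that part all 3 pairs, the others gave 0. For these, 10 splits are too few for a share under 0.05. For the genes changed in both lines, 1 of 100 drawn splits gave as many as 477, with 0 as the highest other. Breaking the real grouping of 1 line left at most 2 genes called in that line, so hardly any could be shared. The draws therefore exclude chance only for no effect in both lines at once. They do not test whether 2 real responses would share genes by chance. For the interaction, 100 of 100 gave at least the real 0 genes, which no split can fall short of, so this decides nothing. The highest count, 2244, came from exchanging the hairpin labels in 1 line, which turns the shared change into a difference, and the next was 127.

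Genes marking MV4-11 varied together between its arrays. From scrambled replicate 1 to 2, 904 genes of the same brightness that differ little between the lines had a median shift of -0.01. The shift of the marker genes was thus not shared by genes of their brightness. Quantile normalization holds such a median near 0 whatever came before it, so brightness or scaling before normalization was not tested. A share of RNA from cells lacking these genes may have differed between arrays. Of the 48 such genes chosen on the CHD4 shRNA arrays, 83.3% were higher in scrambled replicate 2 than in replicate 1. The median shift was 1.22. Any shared regulation would give the same. MV4-11 arrays of the same number also correlated, so this choice of genes was not independent of the scrambled arrays and may raise that share. That the rest of that RNA was like the U937 arrays is argued against, as 10 of 10 genes high in U937 lay below the level this needs, at a median of -2.61 against a bound of -0.63. These 10 genes were chosen as low on the CHD4 shRNA arrays of MV4-11, which makes low values in its scrambled arrays likely. The count of 10 therefore adds little, although a share of RNA like U937 would hold any such gene near or above the bound. Shared regulation of these genes was not tested, and since scrambled arrays of different lines correlated at a mean r of 0.987, the identity of the MV4-11 cultures and a share of cells unlike U937 in them stay open, which bears on what the 477 shared genes and the comparison of the responses mean.

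Large rises started from lower levels than large falls. The starting levels, read in the other line's scrambled arrays, had a median percentile of 38.0 for 2-fold rises and 62.1 for falls in U937, and of 40.1 and 70.8 in MV4-11. Noise of dim probe sets is argued against: 70% of the 40 U937 rises from the dimmer part of the genes were also called as rises in MV4-11. That dimmer part was read in the MV4-11 scrambled arrays, which are also the baseline of these calls, and this favours them. Of all 320 U937 rises, chosen without regard to that level or to a 2-fold change, 63.75% were called as rises in MV4-11. Among the 139 changes of brighter genes rises made up 38.8%, but this share follows from the pattern itself, so it decides nothing. A floor that keeps dim genes from falling further stays open.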
